A study of Drosophila melanogaster with 2 samples.

How the data were processed

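The measurement was chromatin immunoprecipitation followed by sequencing (ChIP-seq) of Ssrp in whole Drosophila melanogaster embryos. Ssrp is a subunit of FACT, the histone chaperone that takes nucleosomes apart and rebuilds them as polymerases pass, and its partner in FACT is the Spt16 protein encoded by dre4. Per the labels, Ssrp carried green fluorescent protein (GFP) at its C-terminal end and was precipitated with an antibody against GFP. The embryos were of mixed sex and 0 to 16 h old. Chromatin was sheared by sonication, and the labels give a size range of 200 to 800. The 2 samples were biological replicates from separate collections of embryos, per the labels, and formed 1 group. Control libraries were not analysed here.

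The authors deposited 4 peak lists, and the text deposited with the samples places all of them on the dm6 assembly. That text derives each replicate list from the alignment of that replicate and from 1 further alignment that all lists share. It derives the pooled list from both alignments, and the list passed by the irreproducible discovery rate (IDR, a measure of how well replicate rankings hold together) from the replicate lists and the pooled list. The aligner, the peak caller, the IDR threshold and the nature of the shared alignment are not given in the sources used here. The deposited signal of a peak is the value set by the authors' peak caller, on a scale of its own in each list, so it was used only to describe and rank peaks within a list. The deposited −log10 of the q-value was capped: 3564 peaks of the pooled list shared its highest value, 3.85. The deposited p-value column held no values. The deposited peaks also give a summit, and 4 summits of the IDR list lay outside their own peak and were set to its nearest base. The files give no read numbers, so the depth of each replicate is unknown, and the intervals printed are binomial (Wilson, 95%) and cover the counting error of peaks or genes only.

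Chromosome lengths of the reference assembly (release 6) were compared with the highest peak coordinates, and no peak lay beyond the end of its chromosome. Genes, transcripts and transcription start sites (TSSs) came from the Ensembl annotation, release 115, on the same assembly, without transposable elements. This left 18277 genes on chromosomes 2L, 2R, 3L, 3R, 4, X and Y, of which 13968 were protein-coding and 3979 were noncoding. No peak lay off these 7 chromosomes. Each summit was placed in the first class that held it, in the order promoter (within 500 bp of a TSS), 5′ UTR, coding exon, 3′ UTR, noncoding exon, intron and intergenic.

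The tests, the gene lists, the sequence elements and the rule for named genes were fixed before the data were examined. Replicate overlap compared the 5445 strongest peaks of each replicate, as many as the IDR list holds, and counted a pair as shared when the overlap covered at least 50% of each peak. Chance levels came from 1000 circular shifts along each chromosome, so the smallest p possible was 0.001 for a one-sided and 0.002 for a two-sided test. Signals were compared with a two-sided permutation test of 100000 resamples. The share of promoter summits downstream of the TSS was set against 50% with a two-sided exact binomial test, leaving out TSSs with one on the opposite strand within 1000 bp. Chromosomes were tested against their share of the assembled length with a two-sided exact binomial test. A gene counted as bound when an IDR summit lay within 500 bp of any of its TSSs. Each of 27 gene lists, 22 of protein-coding and 5 of RNA genes, was set against all other genes of its kind with a two-sided Fisher exact test. Each of 13 sequence elements was sought within 100 bp of 1 TSS per protein-coding gene, on either strand, and bound promoters were set against unbound ones with the same test. That TSS was the one nearest a summit for genes with a peak and the most 5′ one for genes without. All adjusted p-values follow Benjamini and Hochberg within each family, and the threshold was 0.05. One peak can count for neighbouring genes, so genes within a list are not fully independent. Odds ratios of single lists and elements were computed with a small constant added to each count. Lists with no bound gene therefore have ratios above zero, and a ratio near 1 can lie on the other side of it than the raw shares.

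The rule for named genes took the genes of the 15 IDR peaks with the highest signal, up to 3 bound members of each list by signal, and Ssrp and dre4 whatever their values. Of the listed symbols, 1 had no gene in the annotation. Alternatives were the overlap rule, the number of peaks, uniform placement in place of shifts, promoter windows of 250 and 1000 bp or the whole gene body, the 2722 strongest IDR peaks, the 10890 strongest pooled peaks, the nearest TSS only, each replicate alone, TSSs as the denominator, element windows of 50 and 200 bp, and a correction for GC content. Comparison with the weaker pooled peaks, and the most 5′ TSS for every gene, were alternatives added after seeing the data.

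All steps ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. They were tested on simulated data first. In simulated lists made with 70% of strong peaks shared, the overlap of 5445 peaks came out at 70.6%. With 40% of peaks planted at promoters and the others at random, 48.4% of 5445 were found there, against 13.5% for shifted peaks. With 20% of the planted promoter summits downstream of the TSS, 27.7% of 1575 were found there, a count that includes peaks placed at random. Among 18277 genes, a weight of 8 planted on ribosomal protein genes was recovered as an odds ratio of 10.7, and 1 of 25 lists with no planted change was called. Among 13968 promoters, a weight of 3 planted on the DRE element was recovered as an odds ratio of 3.74, while 5 of 12 elements with no planted change were called beside it.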

Results

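Binding of Ssrp-GFP was measured by ChIP-seq in 2 biological replicates of whole Drosophila embryos aged 0 to 16 h. The replicate lists and the pooled list held 30000 peaks each, and the IDR list held 5445 peaks, which were the 5445 strongest peaks of the pooled list. The commonest peak width was 396 bp in replicate 1, in the pooled list and in the IDR list, and 376 bp in replicate 2. Within the IDR list the signal ran from 157 to 5979 with a median of 292, and its peaks covered 1.28% of the 7 chromosomes. The design has no second group, so the comparisons concern the replicates, the place of the peaks in the genome and the genes they mark. Read depth is unknown. Here bound means only that a gene has an IDR summit at a TSS, since no control without the tagged protein was analysed here and it is open whether each peak depends on that protein.

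The strongest sites were shared by both replicates. The highest peak of every list, with a signal of 5979 in the IDR list, lay at the promoter of CG14100 (FBgn0036889) on 3L, from 19590410 to 19590823, with its summit at -97 bp from the TSS. The next sites were the promoter of px (plexus), the shared promoter of Art3, an arginine methyltransferase gene, and mRpS10, a mitochondrial ribosomal protein gene, and the promoter of mRpL41, another gene of that ribosome. Their signals were 4390, 4373 and 4342, and they ranked 2, 5 and 3 in replicate 1 and 4, 2 and 3 in replicate 2. Of the 15 strongest peaks, 11 had their summit in a promoter, 3 in an intron and 1 between genes.

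A promoter of ph-p, which encodes a Polycomb group protein, held the peak of rank 6 on X (2137154 to 2137551, signal 4005), and that of rank 8 lay on 3L (22878698 to 22879102, signal 3957) at the neighbouring promoters of Chro, which encodes a chromodomain protein, and Ssl1, a subunit of the general transcription factor TFIIH. Its summit was inside Chro, 101 bp downstream of the TSS. HmgD and HmgZ, neighbouring genes for HMG-box proteins on 2R, shared an intronic peak (21703183 to 21703686, signal 3405, rank 14). Other intronic summits lay in CG11050 and in ush, a GATA cofactor gene with a role in dorsoventral patterning, with signals of 4058 and 3979. The intergenic peak on 2R (13035145 to 13035523, signal 3930) lay 11916 bp from its nearest TSS, that of CG13323. The promoters of Tcs5 and CHMP2B, Ugalt, CG5611 and Mtl, CG18549 and PNPase completed the group, with signals of 3733, 3694, 3693, 3472 and 3363.

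Over the genome, 62.3% (95% interval 61.0 to 63.6, 3393 peaks) of the 5445 strongest peaks of replicate 1 were shared with those of replicate 2. Shifted lists shared 1.00% ± 0.147 (SD of the shifts; one-sided permutation p = 0.001, the smallest possible). Both replicate lists also draw on the same further alignment, and the shifts cannot tell how much of the overlap comes from it. Across the 4212 IDR peaks matched in both lists, signals had a Spearman rho of 0.805 (bootstrap interval 0.788 to 0.820), a description across peaks, which are not independent replicates.

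The genes of both FACT subunits were looked up in every list. At dre4, which encodes the other FACT subunit, an IDR peak lay on 3L from 1876302 to 1876697 with its summit at -188 bp from the TSS, a signal of 312, or 1.07 times the median of the list, and rank 2504. The same promoter held a peak of rank 3844 in replicate 1 and of rank 2044 in replicate 2. At Ssrp (2R, 23806361 to 23809004, minus strand), neither the IDR list nor the pooled list nor replicate 1 had a summit in the gene or within 500 bp of it. Replicate 2 had 1, of rank 9577, with a signal of 46.6.

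Promoters and introns held most of the peaks. Promoters had 40.7% of IDR summits (95% interval 39.4 to 42.0, 2214 summits) against 13.6% ± 0.669 of shifted peaks, a ratio of 3.0 (two-sided permutation test, adjusted p = 0.0035). The replicates gave 41.0% ± 2.04 (SD, n = 2). Introns had 40.4%, close to the 39.4% of shifted peaks (permutation test, adjusted p = 0.401), and intergenic sequence had 16.5% against 27.3% (ratio 0.606, adjusted p = 0.0035). The intronic ratio passed the test in both directions, at 1.11 with promoters of 250 bp and at 0.916 with 1000 bp. Among positions matched to the summits on GC content 44.3% were intronic and 30.1% intergenic (ratios 0.910 and 0.550), and both observed shares lay below every matched draw. Promoter peaks were also stronger, with a median signal of 325 against 270 for the other IDR peaks, a ratio of 1.2 (two-sided permutation test, p = 1e-05, the smallest possible).

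Coding exons were nearly devoid of summits. They held 9 of 5445, or 0.165% (95% interval 0.0870 to 0.314), against 13.7% ± 0.709 of shifted peaks, a ratio of 0.0121 (permutation test, adjusted p = 0.0035). Against positions matched to the summits on GC content, 2.39% of which lay in coding exons, the ratio was 0.0692. The strongest peaks of the replicates gave 0.386% ± 0.442 (SD, n = 2), with 38 summits and a ratio of 0.0510 in replicate 1 alone and 4 summits and a ratio of 0.00537 in replicate 2 alone. The 3′ UTRs had 0.937% against 4.43% and the 5′ UTRs outside promoters 0.422% against 0.782%, both below shifted peaks (permutation test, adjusted p = 0.0035 and 0.0056), while noncoding exons had 0.900% against 0.817% (adjusted p = 0.573), though with promoters of 250 bp their ratio was 1.33 and passed. Positions matched on GC content had 8.15% in 3′ UTRs (ratio 0.115). They had 0.520% in 5′ UTRs (ratio 0.813, draws from 0.239% to 0.845%), so the 5′ UTR share lay within the matched draws. The 24555 weaker peaks of the pooled list reached down to a −log10 q of 0.352, against 2.62 in the IDR list, and need not all be binding sites. They did not share the coding exon deficit, with 15.9% of their summits there. In promoters they had 21.8%, between the 13.6% of shifted IDR peaks and the 40.7% of IDR peaks. Intergenic sequence held 12.5% of them, below the 27.3% of shifted IDR peaks. Against those weaker peaks, a comparison added after seeing the data, the promoter ratio was 1.87, the intergenic ratio turned to 1.32 and the intronic ratio to 0.961, each past the threshold.

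**Figure D1:**
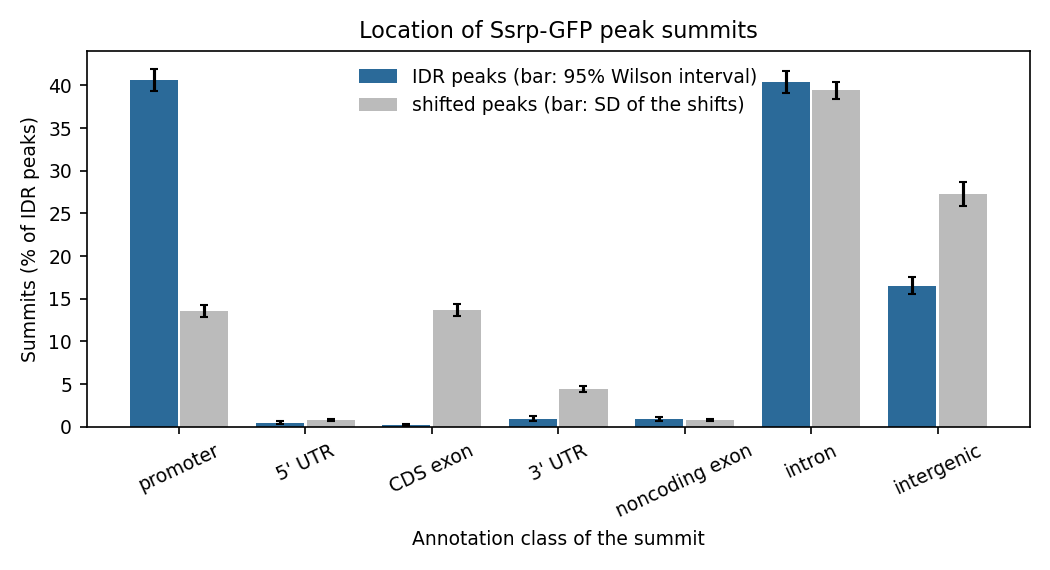
Percent of summits in each annotation class (bars) for the 5445 IDR peaks, with 95% Wilson intervals, and for the same peaks shifted along their chromosomes, with the SD of 1000 shifts. Promoters hold 40.7% of IDR summits against 13.6% of shifted ones, and coding exons 0.165% against 13.7%.

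Summits lay in stretches poor in G and C. In the 101 bp around an IDR summit the mean GC content was 30.0% ± 7.96 (SD over peaks), against 43.1% ± 7.81 at 600 bp on either side and 42.2% over the chromosomes. GC content was lower at the summit than in its flanks for 87.9% of the peaks. The means were 30.0% for promoter, 29.8% for intronic and 29.4% for intergenic summits, 31.3% and 29.5% for the strongest peaks of replicates 1 and 2, and 41.4% for the weaker pooled peaks. Measurements of GC content, repeated sequence and gene length were chosen after the peaks had been looked at.

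**Figure D2:**
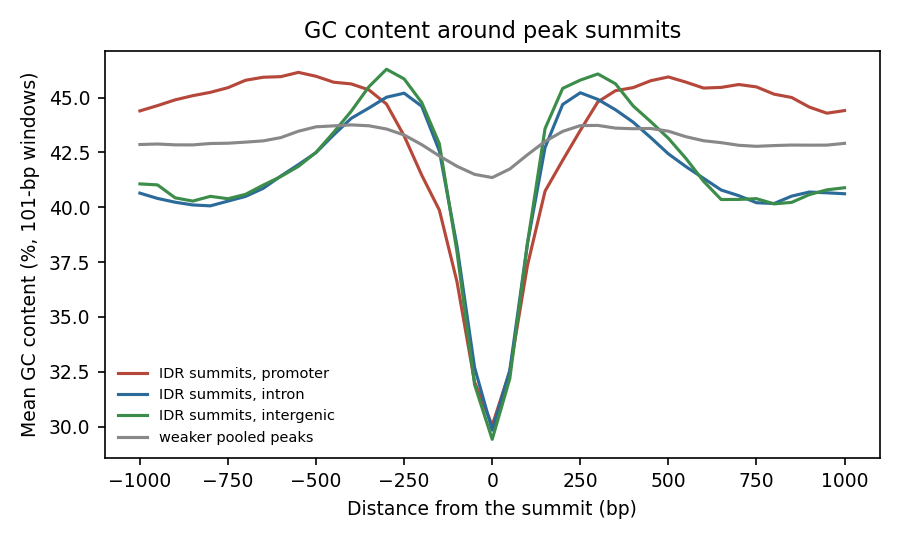
Mean GC content (percent, 101-bp windows, vertical axis) by distance from the summit (bp, horizontal axis) for IDR summits in promoters, introns and intergenic sequence and for the weaker pooled peaks. The IDR curves fall to 30.0%, 29.8% and 29.4% at the summit, while the weaker peaks stay at 41.4%.

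At promoters, the summits lay on the upstream side of the start site. Among 1187 summits near TSSs of 1 strand only, 17.9% (95% interval 15.8 to 20.1, 212 summits) were downstream of the TSS, and the median position was -181 bp with quartiles at -287 and -79 bp (two-sided exact binomial test, p = 2.99e-117). Among elongation and chromatin factors, the summit lay at -141 bp from the TSS of brm, the ATPase of the Brahma remodelling complex, at -208 bp at Chd1, another remodeller, and at -186 bp at TH1, a subunit of the pausing factor NELF. For the replication genes RnrS and Mcm2 it lay at -186 and -182 bp. Other promoter summits lay downstream of the TSS, 22 bp at RpL7, 80 bp at PNPase, 101 bp at Chro, 21 bp at Rpn3, 90 bp at Hsp83 and 209 bp at betaTub56D. Positions in the same windows with the GC content of the summit, the summit and its neighbours included, were downstream in 28.5% of cases.

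**Figure D3:**
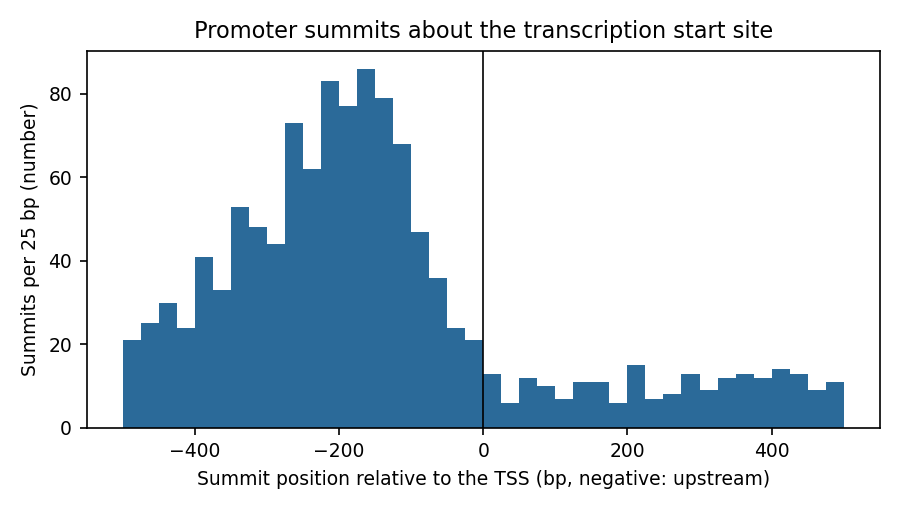
Number of IDR summits per 25 bp (vertical axis) by position relative to the TSS (bp, horizontal axis, negative upstream) for the 1187 summits near TSSs of 1 strand. Summits gather left of the start site, with the median at -181 bp and 17.9% of them to its right.

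Chromosome X carried 44.1 IDR peaks per Mb, 2L 43.1 and 3L 42.9, each more than its length would give (observed over expected 1.11, 1.09 and 1.08; exact binomial test, adjusted p = 0.000341, 0.00417 and 0.00368). Chromosome 2R had 36.7 per Mb, fewer than its length would give (0.926, exact test, adjusted p = 0.0112), and 3R had 39.0 (0.985, adjusted p = 0.553). The small chromosome 4, which is largely heterochromatic, had 9 peaks, or 6.68 per Mb (0.169, exact test, adjusted p = 4.26e-13), and the Y had 0, as it had among the weaker pooled peaks (exact test, adjusted p = 1.38e-63). The weaker pooled peaks were few on chromosome 4 too, 67 or 0.273% of them, where its length would give 0.980%. Their share did not differ from that of the IDR peaks past the threshold (Fisher exact test, p = 0.180). The deficits on 4 and Y are therefore not particular to the IDR peaks. The expected shares take in 0.980% for chromosome 4 and 2.67% for Y, so these deficits raise the ratios of all other chromosomes. A test by length without 4 and Y was not run, so how much of the excess on X, 2L and 3L goes beyond that is open. In embryos of mixed sex X and Y are below autosomal dose, and neither dose nor repeated sequence was corrected for. In the 2 replicates X had 43.2 ± 2.31 peaks per Mb and 4 had 8.53 ± 2.62 (SD). In replicate 1 alone neither X nor 2R passed the test and chromosome 4 stood at 0.262, and with TSSs in place of length 2L stood at 0.990.

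Among the protein-coding lists, 5 were bound more often than other genes: cytosolic and mitochondrial ribosomal proteins, constitutive chaperones, replication and cell cycle genes, and elongation and chromatin factors. Of 18277 genes 2977 were bound, among them 2694 (19.3%) of the protein-coding genes. The cytosolic ribosomal protein genes had 52 of 92 bound (56.5%, 95% interval 46.3 to 66.2; odds ratio 5.51, Fisher exact test, adjusted p = 3.07e-14), and RpL34b, RpS27 and RpL7 had the highest signals, 1028, 951 and 653. Constitutive chaperones had 11 of 16 bound (68.8%, odds ratio 8.78, exact test, adjusted p = 0.000121), with Hsc70-5, the mitochondrial Hsp70, at 1064, and CCT3 and Hsc70-4 at 467 and 466. Mitochondrial ribosomal protein genes had 25 of 73 bound (34.2%, odds ratio 2.21, exact test, adjusted p = 0.00760), led by mRpS10, mRpL41 and mRpS23.

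Of the replication and cell cycle genes 14 of 28 were bound (50%, odds ratio 4.20, exact test, adjusted p = 0.000953), including CycE, which drives entry into S phase, at 1163, RnrS, a ribonucleotide reductase subunit, at 1148, and Mcm2, of the replicative helicase, at 606. Of the elongation and chromatin factors, the group to which FACT itself belongs, 11 of 27 were bound (40.7%, odds ratio 2.92, exact test, adjusted p = 0.0278), with brm at 1814, TH1 at 1076 and Chd1 at 803. In the replicates these lists stood at 46.4% ± 5.05 and 44.4% ± 0 (SD, n = 2). With summits counted anywhere in the gene body, none of the 5 protein-coding lists was called above the others. The odds ratio was 1.56 for cytosolic ribosomal proteins and 0.148, below other genes, for mitochondrial ones. The mitochondrial ones are short, with a median length of 909 bp. They held 0 summits outside promoters, where lists matched on gene length had a mean of 0.765. Among the 2722 strongest IDR peaks and the 10890 strongest pooled peaks the odds ratio was 2.71 and 10.7 for cytosolic ribosomal proteins and 5.94 and 14.2 for constitutive chaperones, and for the chaperones it was 5.37 in replicate 2 alone. Some calls also ended elsewhere: with each peak given to its nearest TSS the odds ratio was 1.27 for mitochondrial ribosomal proteins and 2.73 for elongation factors, and among the 2722 strongest peaks it was 2.17 for replication genes.

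Chemoreceptor, cuticle protein, male accessory gland and male germline genes were bound less often than other genes. None of the 180 chemoreceptor genes (Fisher exact test, adjusted p = 7.22e-16) and none of the 123 cuticle protein genes (adjusted p = 4.66e-11) was bound, with upper 95% limits of 2.09% and 3.03%. Of the male accessory gland genes 1 of 45 was bound (Sfp26Ad, exact test, adjusted p = 0.00369), and of the male germline genes 1 of 39 (Mst85C, adjusted p = 0.0103). The germline call ended among the 2722 strongest peaks and with the nearest TSS only (odds ratios 0.291 and 0.242). The replication-dependent histone genes, which are expressed in S phase, had 0 of 111 bound (exact test, adjusted p = 5.42e-10), but only 0.876% of the 32-base sequences around their TSSs occur once in the chromosomes, against 98.4% around 500 random genes.

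The 4 lists of body plan regulators passed no test in the main comparison of promoters. Hox genes had 0 of 8 bound, segmentation genes 2 of 30 (nkd and ptc), dorsoventral patterning genes 2 of 24 (tin and htl), and proneural and neuroblast genes 4 of 22, including E(spl)m3-HLH, E(spl)m7-HLH and E(spl)mdelta-HLH of the Notch-responsive cluster, at 1670, 1264 and 1140 (Fisher exact test, adjusted p = 0.451, 0.158, 0.399 and 1). With the whole gene body counted, Hox genes had an odds ratio of 11.3 and dorsoventral patterning genes 4.43, both above the other genes. Against genes of matched length neither list was called, with summits outside promoters at 1.13 and 2.47 times the matched mean (permutation, adjusted p = 1 and 0.160). Among the 10890 strongest pooled peaks, segmentation genes and chorion genes were called below other genes (odds ratios 0.214 and 0.0739). Differentiated neuron genes had 2 of 25 bound (elav and comt, exact test, adjusted p = 0.292), muscle structural genes 4 of 25 with Msp300, sls and Tm1 the strongest (adjusted p = 0.869), and chorion and vitelline membrane genes 0 of 16 (adjusted p = 0.0979).

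In the main comparison, 5 further lists did not pass. Translation factors had 11 of 34 bound, led by eIF6 at 1832, eIF3c and eIF5B (Fisher exact test, adjusted p = 0.131), complex I subunits 12 of 40, led by ND-MWFE, ND-ASHI and ND-51 (adjusted p = 0.158), and proteasome subunits 6 of 32, led by Rpn5, Rpn3 and Rpn11 (adjusted p = 1). Heat shock genes had 4 of 17 bound, with Hsp27 at 1749 and Hsp26 and Hsp83 lower (exact test, adjusted p = 0.650), and actins and tubulins 4 of 8, with gammaTub23C, Act5C and betaTub56D (exact test, adjusted p = 0.0963). Translation factors were called above other genes among the 10890 strongest pooled peaks (odds ratio 3.90), and actins and tubulins with promoters of 1000 bp (5.38).

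**Figure D4:**
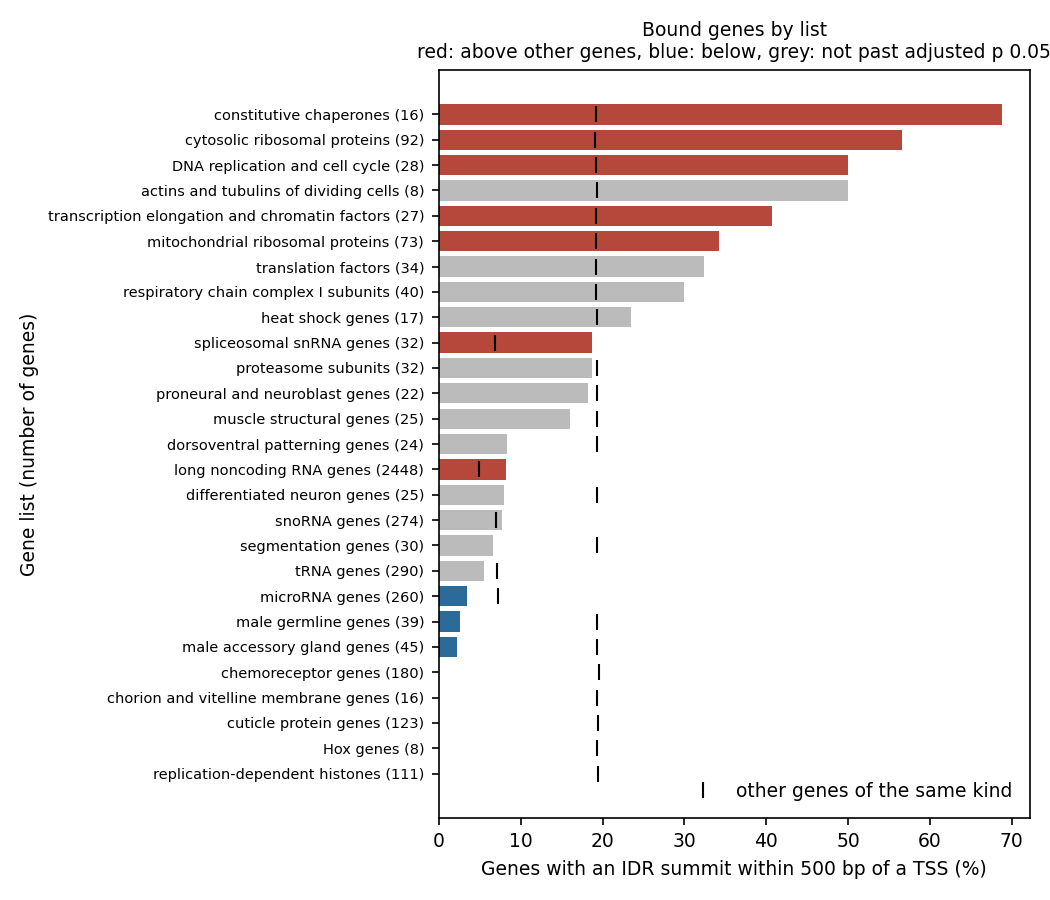
Percent of genes bound (horizontal axis) for each of the 27 lists (vertical axis, number of genes in parentheses), with a tick for the other genes of the same kind. Constitutive chaperones and cytosolic ribosomal proteins reach 68.8% and 56.5%, and 5 lists stand at 0.

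Among RNA genes, long noncoding RNA genes were bound more often than other noncoding genes, 202 of 2448 (8.25% against 4.96%, odds ratio 1.72, Fisher exact test, adjusted p = 0.000312), and so were spliceosomal snRNA genes, 6 of 32 (odds ratio 3.31, adjusted p = 0.0443), with snRNA:U5:63BC, snRNA:U6:96Ab and snRNA:U6:96Ac the strongest. The U6 genes named shared the same peak (3R, 24556874 to 24557269), so the 6 genes stand for fewer sites. Signals at U5:63BC and at the U6 genes were 221 and 211, or 0.758 and 0.724 times the list median. At U5:63BC and U6:96Ab the summit lay 222 and 380 bp downstream of the TSS, past the end of the gene. MicroRNA genes were bound less often, 9 of 260 (odds ratio 0.484, exact test, adjusted p = 0.0377), with mir-9377, mir-ban and mir-2491 the strongest. The annotated mir-9377 (12665217 to 12665268) and mir-ban (642208 to 642288) are short, and their summits lay 425 and 426 bp past the annotated start, outside the gene. For microRNA and snoRNA genes the annotated start need not be where transcription starts, so bound means only a summit near it. tRNA genes, 16 of 290 bound, and snoRNA genes, 21 of 274, were not called (exact test, adjusted p = 0.438 and 0.701). Among the 10890 strongest pooled peaks both were called above the others (odds ratios 1.63 and 2.29), and with promoters of 1000 bp so were snoRNA genes (1.92). In other settings snoRNA genes were called below the others, among the 2722 strongest peaks (0.332), in replicate 2 alone (0.466) and over gene bodies (0.189), and tRNA genes over gene bodies (0.0349). The calls above and below were not firm. That of the snRNA genes ended in replicate 2 alone (odds ratio 1.81), with promoters of 250 and 1000 bp (3.22 and 2.69), among the 2722 strongest peaks (0.414) and over gene bodies (0.335). That of long noncoding RNA genes ended in replicate 1 alone (1.19, against 2.61 in replicate 2 alone), with promoters of 250 bp (1.46) and among the 10890 strongest pooled peaks (0.863). It held with larger odds ratios among the 2722 strongest peaks (3.64) and with the nearest TSS only (2.99), and over gene bodies the ratio was 17.2. That of microRNA genes ended in replicates 2 and 1 alone (0.494 and 0.655), with promoters of 250 and 1000 bp (0.665 and 0.635), among the 10890 strongest pooled peaks (0.760) and with the nearest TSS only (0.420). The gene-body ratios of RNA genes were not matched on gene length. Short genes leave little room for a summit, and only 6 of 1531 noncoding genes outside the long noncoding list held one. Those ratios therefore cannot be read as a preference for or against a list.

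Of the 13 elements, 8 were more frequent in bound than in unbound promoters. Motif 7, found in promoters of housekeeping genes, was present within 100 bp of the TSS in 14.6% (95% interval 13.3 to 16.0) of 2694 bound and 5.82% of 11274 unbound promoters (odds ratio 2.77, Fisher exact test, adjusted p = 9.83e-46). The E-box CAGCTG was present in 17.8% against 12.8% and DRE, the site of the factor DREF, in 9.80% against 7.16% (odds ratios 1.48 and 1.41, exact test, adjusted p = 1.47e-10 and 1.91e-05). Motif 1, GAGA, CACGTG, TCT and Motif 6 were also more frequent, with odds ratios of 1.53, 1.52, 1.51, 1.23 and 1.40. Bound and unbound promoters differed in how their TSS was chosen. With the most 5′ TSS for every gene, these 8 elements stayed more frequent, with GAGA lower at 1.32 and Motif 1 higher at 1.74.

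Matches to the TATA box, the Initiator and DPE were less frequent in bound promoters. They were counted on either strand anywhere within 100 bp of the TSS. The values are thus frequencies of short words, many of which can match by chance, and not of elements at a working position. The TATA box was matched in 3.19% of bound and 8.91% of unbound promoters (odds ratio 0.339, exact test, adjusted p = 1.29e-26), the Initiator in 22.2% against 31.3% (0.625, adjusted p = 7.58e-21), and the short DPE consensus in 74.6% against 78.6% (0.799, adjusted p = 1.93e-05). For the TATA box the odds ratio was 0.247 within 50 bp and 0.549 within 200 bp. The sites of Zelda, the activator of the early embryonic genome, and the heat shock element showed no difference past the threshold (exact test, adjusted p = 0.360 and 0.836). GC content of the windows was 41.5% in bound and 41.7% in unbound promoters. In simulated lists where DRE was the only element planted, 5 of the 12 other elements were also called. Changes on ribosomal protein and chemoreceptor genes were planted in the same lists, so these calls cannot be laid to DRE alone. Among the 2722 strongest peaks, DRE, Motif 1 and Motif 6 no longer passed (odds ratios 1.13, 1.06 and 1.19), Motif 6 passed neither within 50 bp (1.49) nor in either replicate alone, and DPE did not pass within 200 bp (0.835).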

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

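Comparison with the weaker pooled peaks, and the most 5′ TSS for every gene, were the alternatives in this part chosen after the result was seen. Of the alternatives for results that answer a comparison, 90 kept the direction and side of the threshold of the main value or stayed near it, and 12 did not. For single lists and elements these numbers were 258 and 70. These counts take the printed odds ratios, which carry a small added constant. In the main comparison 18.2% of proneural and 18.8% of proteasome genes were bound, against 19.3% of other genes. Only the constant put their main ratios above 1, so ratios below 1 given for them here are no change of direction. The cause was not tested for any value that follows, except that counting whole gene bodies changes which summits are counted. The intronic ratio passed at 1.11 with promoters of 250 bp, at 0.916 with 1000 bp and at 0.961 against the weaker pooled peaks, and it did not pass at 0.944 among the 2722 strongest peaks or at 0.980 to 1.05 with 1 replicate left out; the intergenic ratio was 1.32 against the weaker pooled peaks. Observed over expected peaks were 0.990 on 2L with TSSs as denominator, and with 1 replicate left out 0.891 to 0.952 on 2R, 0.991 to 1.01 on 3R and 1.05 to 1.13 on X. With whole gene bodies, 3 lists stood above other genes in place of 7, and the odds ratios were 0.988 for replication genes, 11.3 for Hox, 1.93 for differentiated neuron, 4.43 for dorsoventral, 0.148 for mitochondrial ribosomal protein, 2.40 for muscle, 0.878 for proneural, 0.854 for proteasome, 0.467 for complex I, 1.22 for segmentation, 0.189 for snoRNA and 0.335 for snRNA genes. With promoters of 250 bp they were 0.408 for proneural and 0.840 for snoRNA genes, and with 1000 bp 1.14 for muscle, 0.831 for proneural and 0.838 for proteasome genes. Among the 2722 strongest peaks, 5 elements in place of 8 were more frequent in bound promoters, and the odds ratios were 1.57 for muscle, 0.889 for proteasome, 0.332, which passed, for snoRNA and 0.414 for snRNA genes and 0.718 for the heat shock element, which had 0.837 within 50 bp. Among the 10890 strongest pooled peaks they were 0.814 for heat shock, 0.863 for long noncoding RNA, 1.19 for muscle, 0.593 for proneural and 1.63 for tRNA genes. With the nearest TSS only they were 1.31 for muscle, 0.435 for proneural, 0.511 for proteasome and 0.711 for snoRNA genes. With 1 replicate left out they ran from 0.864 to 1.13 for muscle, 0.466 to 1.59 for snoRNA and 0.549 to 1.00 for tRNA genes, and from 0.852 to 1.14 for the heat shock element. Replicate overlap, the share of promoters and coding exons, the upstream side of the summits and the higher signal at promoters kept their direction and call in every alternative run, though the coding exon ratio ran from 0.00537 to 0.0510 with 1 replicate left out. No paired analysis was possible because the samples form 1 group. Read depth is unknown, so it is open how many weaker sites a deeper library would add.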

Other observations

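All tests in this part were chosen after the locations of the peaks, the gene list counts and the summit sequences had been seen. Outside promoters lay 3231 IDR summits, at a median of 2720 bp from the nearest TSS (quartiles 1244 and 6087 bp). The protein-coding genes with most of them were kirre, an immunoglobulin adhesion gene of muscle founder cells, with 25, and CG1677, sbb, CG43658, fz2, shn and ush with 17, 14, 13, 12, 12 and 12. The Wnt receptor genes fz2 and fz had 12 and 10, and hth, which encodes a cofactor of Hox proteins, had 11. Of the body plan genes, ush had its 12, Antp 6, nkd 6, vn 6, sog 4, Ubx 3 and ptc 3.

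Long genes of differentiated neurons were nearly empty by the same count. Their 25 genes held 2 summits outside promoters, 1 in an intron of Fas2 and 1 in an intron of VGlut, against a mean of 28.6 (95% of random lists from 12 to 50) in 10000 random lists matched on gene length (two-sided permutation p = 0.0002, the smallest possible; adjusted p = 0.00440 over 22 lists). Heat shock genes held 4 summits summed over genes against 0.258 (permutation, adjusted p = 0.00660), but the call ended with 3 distinct summits (permutation p = 0.00920, adjusted p = 0.101): 1 each in introns of Hsp83 and stv and 1 in the overlapping genes Hsp22 and CG4456. Dorsoventral patterning genes held 27 against 10.9 (permutation p = 0.0218, adjusted p = 0.160), 12 of them in ush alone, and Hox genes 12 against 10.7 (adjusted p = 1). For the 84 genes of the 4 body plan lists together, which held 55 summits or 1.48 times the matched mean (95% of lists from 19 to 60), long gene bodies cannot be told apart from a preference for these genes. In random lists of 25 genes the same test called 3.5% of 200 at an unadjusted threshold of 0.05.

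The peaks were AT-rich at their summits, and bias of the library towards DNA of low GC content could place peaks by sequence alone. Positions of the same chromosomes matched to the summits on GC content argued against that as the whole cause: the observed promoter share was 2.96 times theirs (40.7% against 13.7%, highest of 1000 draws 15.4%) and the coding exon share 0.0692 times theirs (0.165% against 2.39%, lowest draw 1.87%). GC content goes with a part of the coding exon deficit, since shifted peaks had 13.7% there. For the upstream position, matched positions in the same windows were downstream of the TSS in 28.5% of cases, between the bounds of 25% and 35% set before this test. The observed 17.9% lay below the lowest draw, 25.3%. The matched positions include the summit and its overlapping neighbours, which pulls their share towards the observed one. How much of the upstream position goes with GC content is therefore not settled by this test. Of the positions at or below the median GC content of the summits, 3.09% lay in an IDR peak, against 1.28% of all positions; recovery that differs with GC content, open chromatin and an affinity of Ssrp for such DNA all stay open, as does signal that would appear without the tagged protein, and no biological explanation was tested.

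The 5 protein-coding lists called above other genes had 113 of 236 genes bound and the 4 called below, histones left out, 2 of 387, a contrast that follows from choosing the lists by their calls and leaves out those not called, such as proteasome and muscle genes. GC content could separate them, as the lowest GC content in the promoter averaged 21.4% ± 5.47 and 24.2% ± 5.89 (SD over genes). Within 10 strata of that value the common odds ratio was 131 (95% interval 33.2 to 516), against 177 without it. The groups were chosen by the same calls, so a high ratio was built in. The GC value was also taken at the most 5′ TSS only, while bound counts any TSS. GC content as a cause of these calls is therefore not settled. Repeated sequence is no cause for chemoreceptor and cuticle protein genes, since 97.2% of the 32-base sequences around their TSSs occur once. A candidate explanation that stays open, as a hypothesis, is that binding follows gene activity in these embryos; expression was not analysed here, and proteasome genes, 6 of 32 bound, were not above other genes.

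The histone gene cluster on 2L (21416953 to 21541681, 111 genes) had 0 summits in each of the 4 lists, where the mean density of 2L would give 27.3 in the pooled list. Reads that match many copies alike may account for this: 0.876% of the 32-base sequences around histone TSSs occur once, with a median of 23 occurrences, against 99.4% around ribosomal protein TSSs. Binding at the histone genes therefore remains unknown, and how reads with several matches were treated is not given in the sources used here.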
